A study of Homo sapiens with 6 samples.

How the data were processed

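Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in the small cell lung cancer (SCLC) line NCI-H69, called H69 here, and in H69M, a line derived from it. Each line gave an H3K27ac library, an H3K27me3 library and an input library, so each of the 6 groups holds 1 sample. Per the labels' protocols, formaldehyde-fixed chromatin was sonicated and precipitated with the Abcam antibody ab4729 against H3K27ac or the Cell Signaling clone C36B1 against H3K27me3. Libraries were sequenced from paired ends on a NextSeq500, per the labels' protocols. The aligner was Bowtie2 and SAMtools 0.1.19 was used, per the submitters' processing notes, which also name the genome build hg19.

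Each of the 4 antibody libraries had 1 peak list, and the 2 input libraries were not analysed here. The deposited lists give for every peak a chromosome, a start, an end, a name that carries the word MACS and a score. The MACS version, its settings and whether the input served as control are not given in the sources used here. In the 4 deposited lists the score starts at about 50, and in the H3K27ac lists it piles up at 3100, as the negative log of a p-value would, but its definition is not given, so it is treated as a score with no fixed range. The authors' score was used to rank and describe peaks within a list and to sort or filter both lists by the same limits, although a score may not mean the same in lists of different depth. Of the H3K27ac peaks at this ceiling or above it, 3417 in H69 and 6023 in H69M, 174 and 251 have scores above 3100, up to 3233. Peaks in this range cannot be ranked by strength, so where the rule below takes peaks from it, their order is that of the listed score only. The lists hold no read counts, so the depth of each library is unknown and differences in depth or enrichment between the lines could not be removed. A deeper or better enriched library gives more and wider peaks at the same caller threshold. H3K27me3 usually forms wide domains, and peaks with a median width of 185 bp in H69 and 156 bp in H69M cover only the best enriched pieces of such domains.

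Peaks on chromosomes 1 to 22 and X entered the comparisons. Peaks on all sequences other than chromosomes 1 to 22, X and Y were counted apart. Such sequences are called unplaced contigs here, whether or not their names assign them to a chromosome. Peaks on chromosome Y were left out. Coordinates are 1-based on hg19. The gene table at hand lies on another assembly, GRCh38, so no peak was assigned to a gene, and the planned counts of promoter states and the 15 gene lists fixed before the data were examined were not used here. Regions were described instead per chromosome, per 1 Mb bin and in windows known to hold gene clusters. The MHC, HOXA, HOXB, HOXC and protocadherin windows were fixed before the data were examined. A further 13 windows were added after the layout of the lists and the peak numbers per chromosome had been seen, but before any value in them was computed. All of these windows also hold genes outside the cluster that names them. The rule for named regions was also fixed beforehand. For each mark and line it takes the 5 highest scoring peaks with no peak of that mark within 5000 bp in the other line, the 5 bins with the largest difference in covered length in each direction, and the windows. Other regions that are named were chosen after their values were seen, which is said where they appear.

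A peak counted as shared when it overlapped a peak of the other line by 1 bp or more. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only and treat peaks as independent, although neighbouring peaks are not. With 1 library per group there is no estimate of the spread between cultures, so no p-value between the lines was computed. The covered length of a window was set against other windows of the same size, taken at 1 Mb steps across all chromosomes, whose mean covered length of both lines lay within 1.5-fold. The percentile of the log2 ratio (pseudocount 1000 bp for H3K27ac and 200 bp for H3K27me3) among at least 50 such windows describes these libraries and is not a test.

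Overlap of H3K27ac with H3K27me3 was set against 1000 circular shifts of a list by a random distance along each chromosome, a one-sided permutation test that describes these lists and not the conditions. The smallest p these permutations can give is 0.001. Shifts also place peaks in gaps of the assembly and in regions poor in genes, so shifts of 100 to 500 kb were added after the data were seen. The shift procedure was tested on simulated data made from the overlap of the 21638 H69 H3K27me3 peaks with shifted copies of the H69M H3K27ac list. With 800 planted overlapping peaks 20 of 20 runs were called, with 200 planted peaks 17 of 20, and with 0 planted peaks 2 of 20. These runs used 100 shifts each and the full H69M list, whereas the reported tests used 1000 shifts and, between the lines, lists of peaks found only in a line.

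Alternatives fixed beforehand were a score threshold at the H69 median of each mark (212.6 for H3K27ac and 66.92 for H3K27me3), the same number of peaks in both lines (the highest scores of the longer list), an overlap of at least 50% of the shorter peak, merging of peaks closer than 1000 bp (3000 bp for H3K27me3), and 5 Mb bins. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.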

Results

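The data describe 2 histone marks on the same residue in a pair of isogenic SCLC lines, H69 and its derivative H69M, in a study concerned with SCLC cells that differ in MHC class I. H3K27ac marks active promoters and enhancers. H3K27me3 is written by Polycomb repressive complex 2 and marks silenced regions. On chromosomes 1 to 22 and X the H3K27ac lists held 38255 peaks in H69 and 51091 in H69M, and the H3K27me3 lists held 21638 and 37853. Each list comes from 1 library, read depth is unknown, and there are no replicates, so the differences between the lines have no replicate check.

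The first comparison asked where active chromatin differed between H69 and H69M. H3K27ac covered 48.2 Mb in H69 and 76.8 Mb in H69M, a ratio of 1.59, and the ratio was above 1 on all 23 chromosomes, from 1.26 on chromosome 22 to 1.98 on chromosome 4. The largest surpluses of H69M lay on chromosome 17 at 55 to 56 Mb (139 kb covered in H69 and 237 kb in H69M), at 46 to 47 Mb, which holds the HOXB cluster (143 and 237 kb), and at 75 to 76 Mb (82.8 and 162 kb). Chromosome 11 from 12 to 13 Mb (98.2 and 175 kb) and chromosome 15 from 67 to 68 Mb (21.3 and 95.4 kb) followed. H69 had more H3K27ac in fewer bins, and the largest differences lay on chromosome 6 from 41 to 42 Mb (130 kb in H69 and 72.7 kb in H69M) and chromosome 18 from 45 to 46 Mb (65.4 and 20.9 kb). Chromosome 14 from 104 to 105 Mb (97.6 and 54.04 kb) and from 106 to 107 Mb (78.3 and 41.6 kb) and chromosome 16 from 1 to 2 Mb (140 and 107 kb) followed.

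Of the 2757 bins of 1 Mb with any H3K27ac peak, 2451 were covered over a greater length in H69M (88.9%, 95% interval 87.7 to 90.05) and 306 in H69. H69M peaks overlapped 77.5% of the H69 peaks (29632 peaks, 77.0 to 77.9), whereas H69 peaks overlapped 51.6% of the H69M peaks (26352 peaks, 51.1 to 52.01). Sharing depended on the authors' score. Among peaks with a score of 1000 or more, 99.4% of those in H69 and 93.5% of those in H69M were shared, against 51.1% and 20.3% of those with a score under 100. Under equal numbers of peaks the covered length ratio was 1.42.

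**Figure D1:**
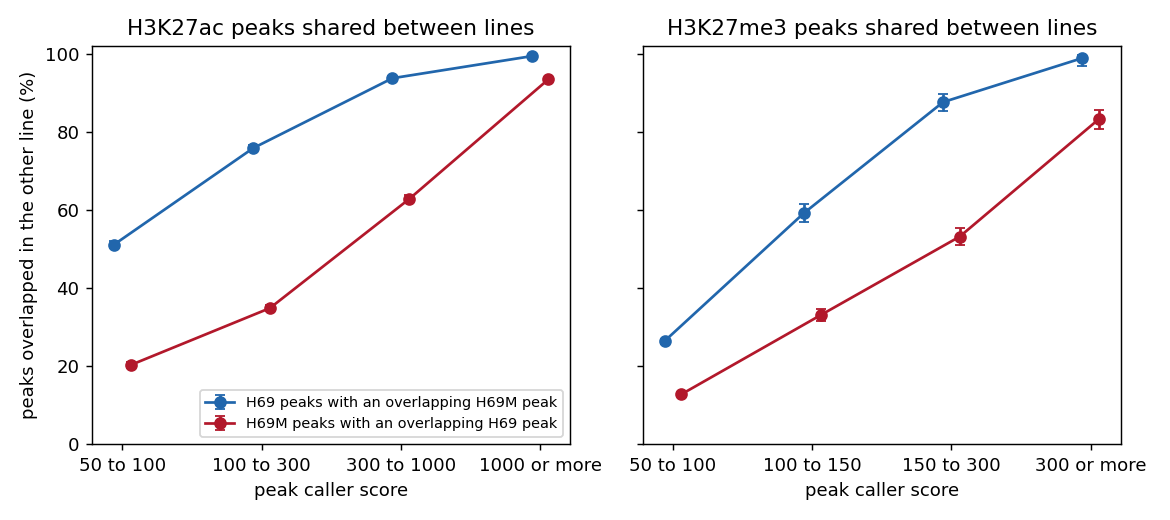
Percent of peaks (vertical axis) that overlap a peak of the other line by 1 bp or more, by the authors' peak score (horizontal axis, score classes), for H3K27ac on the left and H3K27me3 on the right, with H69 in blue, H69M in red and exact 95% binomial intervals as bars. Sharing is lowest among the weakest peaks, where 12.8% of H69M H3K27me3 peaks are shared, and highest among the strongest, where 99.4% of H69 H3K27ac peaks are.

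H3K27ac peaks with no peak of the other line within 5000 bp numbered 4981 in H69 and 17720 in H69M. In H69 the 5 with the highest listed score lay at chromosome 19 45824202 to 45828177, chromosome 5 37837618 to 37841289, chromosome 10 115717615 to 115721011 and chromosome 7 120968695 to 120971149, all with a score of 3100, and at chromosome 18 45934302 to 45937198 with a score of 2888. The chromosome 18 peak falls in the bin from 45 to 46 Mb named above. In H69M they lay at chromosome 6 44007945 to 44012587 (score 3226), chromosome 1 68567525 to 68571061 (3219), chromosome 19 16447865 to 16451584 (3210), chromosome 18 42430030 to 42433352 (3173) and chromosome 6 2970646 to 2972558 (3161). These 5 were taken by the listed score among peaks at or above the ceiling of 3100, and cannot be called stronger than others there. At or above the ceiling 90 H69M peaks had no overlapping H69 peak, a looser rule than none within 5000 bp. How many of the 90 meet the stricter rule was not counted.

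The comparison of H3K27me3 asked where the silencing mark differed. H69M had more of it in regions next to the largest peak-free stretch of a chromosome. Chromosome 8 from 47 to 48 Mb held 326 peaks over 69.2 kb in H69M and was listed with no peak in H69, chromosome 2 from 91 to 92 Mb was covered over 6.06 kb in H69 and 53.8 kb in H69M, and chromosome 4 from 49 to 50 Mb over 4.95 and 51.6 kb. Chromosome 18 from 11 to 12 Mb (42.8 and 86.1 kb) and chromosome 13 from 110 to 111 Mb (19.3 and 60.3 kb) lay away from such stretches. H3K27me3 was lower in H69M on chromosome 2 from 53 to 54 Mb, where 8 peaks over 20.1 kb in H69 had no counterpart, and on chromosome 6 from 30 to 31 Mb inside the MHC (19.7 kb in H69 and 11.955 kb in H69M). It was also lower on chromosome 13 from 112 to 113 Mb (8.57 and 0.837 kb), chromosome 18 from 2 to 3 Mb (10.7 and 4.33 kb) and chromosome 12 from 30 to 31 Mb (8.14 and 2.23 kb).

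H3K27me3 peaks covered 4.91 Mb in H69 and 7.96 Mb in H69M, a ratio of 1.62, or 1.16 under equal numbers of peaks. Chromosome 6 was the only chromosome covered over a shorter length in H69M (283 kb in H69 and 239 kb in H69M, ratio 0.844), and the highest ratio was 4.34 on chromosome X. Of 1978 bins with a peak, 1261 were covered over a greater length in H69M (63.8%, 61.6 to 65.9) and 716 in H69, but under equal numbers of peaks the percent fell below 50, to 44.5%. H69M peaks overlapped 32.6% of the H69 peaks (7051 peaks, 31.96 to 33.2), and H69 peaks overlapped 18.9% of the H69M peaks (7172 peaks, 18.6 to 19.3). Most peaks were weak, with 86.2% in H69 and 81.9% in H69M under a score of 100, while 98.9% of the 270 H69 peaks and 83.3% of the 994 H69M peaks with a score of 300 or more were shared.

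Among H3K27me3 peaks without a counterpart within 5000 bp, 3 of the 5 strongest in H69 lay on chromosome 6, at 1614355 to 1615141 (score 272.6), 100038941 to 100039618 (258.3) and 108487609 to 108488031 (240.5). The others lay at chromosome 5 153857205 to 153857678 (245.5) and chromosome 13 112610641 to 112611386 (244.3). In H69M they lay at chromosome 7 56437924 to 56440960 (score 1805), chromosome 2 162135057 to 162139184 (1801), chromosome 2 91760916 to 91764106 (1644), chromosome 21 11168474 to 11170156 (1126) and chromosome 16 33942573 to 33944783 (1117). Of these 5 H69M peaks, 4 lay within 2 Mb of the largest peak-free stretch of their chromosome, all except the one at 162135057, and none of the 5 H69 peaks did.

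The MHC on chromosome 6, from 28 to 34 Mb, holds the class I genes that present peptides to T cells, the class II genes nearer the centromere and the class III genes between them. The lines differed more in parts of it than over its whole length. In the 1 Mb from 30 to 31 Mb H3K27ac covered 46.6 kb in H69 and 83.5 kb in H69M while H3K27me3 covered 19.7 and 11.955 kb. The neighbouring 1 Mb bins did not share this pattern: from 29 to 30 Mb H3K27me3 covered 5.01 and 9.39 kb and H3K27ac 7.66 and 8.48 kb, and from 31 to 32 Mb H3K27me3 covered 10.7 and 11.3 kb and H3K27ac 75.2 and 77.9 kb. Within the bin from 30 to 31 Mb, the 100 kb from 30.7 to 30.8 Mb had the largest H3K27ac surplus of the window. It held 1 peak over 1.93 kb in H69 and 11 peaks over 23.2 kb in H69M, and there the 10 H3K27me3 peaks of H69 had no counterpart in H69M. These 10 peaks were weak, with a mean score of 67.6 and a highest score of 88.3. Of all H69 H3K27me3 peaks with a score under 100 only 26.4% were shared, so a missing counterpart was the usual case. The 100 kb from 33.9 to 34 Mb showed the largest deficit, with 42.7 kb of H3K27ac in H69 and 19.4 kb in H69M. No H3K27ac peak was listed in either line from 32.2 to 32.8 Mb, toward the class II end, nor in an equally long stretch from 29 to 29.6 Mb.

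Over the whole MHC window H3K27ac covered 308 kb in H69 (200 peaks) and 333 kb in H69M (186 peaks), a ratio of 1.08 against 1.59 over all peaks, and 6.94% of 389 matched windows had a lower ratio. Its last 1 Mb, from 33 to 34 Mb, was the only one with less H3K27ac in H69M (127 and 96.9 kb). There the deficit lay mainly at 33.8 to 33.9 Mb (21.7 and 11.3 kb) and 33.9 to 34 Mb (42.7 and 19.4 kb). The low ratio thus rests in large part on the end of the window, and a ratio without that end was not computed. H3K27me3 covered 63.4 kb in H69 (301 peaks) and 59.5 kb in H69M (357 peaks), a ratio of 0.939 against 1.62 over all peaks. This ratio lay at percentile 2.99 of 134 matched windows, but above the 0.844 of chromosome 6 as a whole. Under equal numbers of peaks it was 0.623. The 100 kb bins and the stretches without H3K27ac were chosen after the values of the window were seen.

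**Figure D2:**
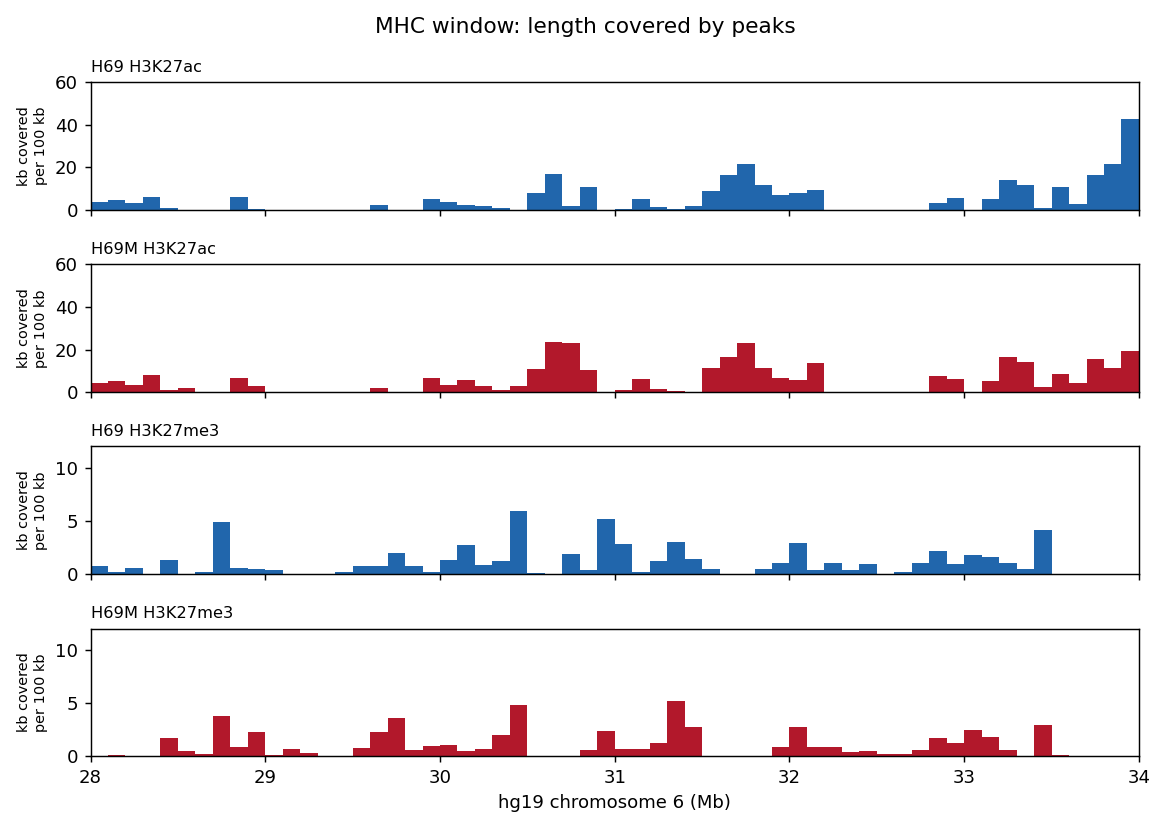
Length covered by peaks (vertical axis, kb per 100 kb) along the MHC window of hg19 chromosome 6 (horizontal axis, Mb), with a panel for each line and mark, H69 in blue and H69M in red, and a wider scale for H3K27ac than for H3K27me3. From 30.7 to 30.8 Mb H3K27ac covers 1.93 kb in H69 and 23.2 kb in H69M, and neither line has an H3K27ac peak from 29 to 29.6 Mb or from 32.2 to 32.8 Mb.

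In the other windows the covered length ratios of the marks lay farthest apart on chromosome 9 from 21 to 22 Mb, which holds the type I interferon genes, secreted antiviral cytokines, beside other genes. H3K27ac there went from 5 peaks over 8.37 kb in H69 to 33 peaks over 33.0 kb in H69M (ratio 3.94, percentile 93.0 of 726 matched windows). H3K27me3 went from 22 peaks over 4.56 kb to 9 peaks over 1.72 kb (ratio 0.377, percentile 4.75 of 295). These H3K27me3 peaks were mostly weak, with mean scores of 74.9 in H69 and 90.5 in H69M. The strongest in H69 (score 168.5) overlapped an H69M peak (131.9). The strongest in H69M (183.6) overlapped an H69 peak with a lower score (101.4). It lay under an H69M H3K27ac peak with a score of 3100, at 21558310 to 21560864, that had no H69 counterpart. At that site H3K27me3 was therefore listed in both lines and not lost. Under equal numbers of peaks H3K27ac had 5 and 19 peaks (ratio 2.97) and H3K27me3 had 22 and 7 (ratio 0.328). The H3K27ac surplus lay mostly between 21.5 and 22 Mb, with 3 peaks in H69 and 29 in H69M, against 2 and 4 peaks between 21 and 21.5 Mb. The interferon genes lie toward the lower-coordinate end of the window. All 5 H69 peaks overlapped an H69M peak.

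**Figure D3:**
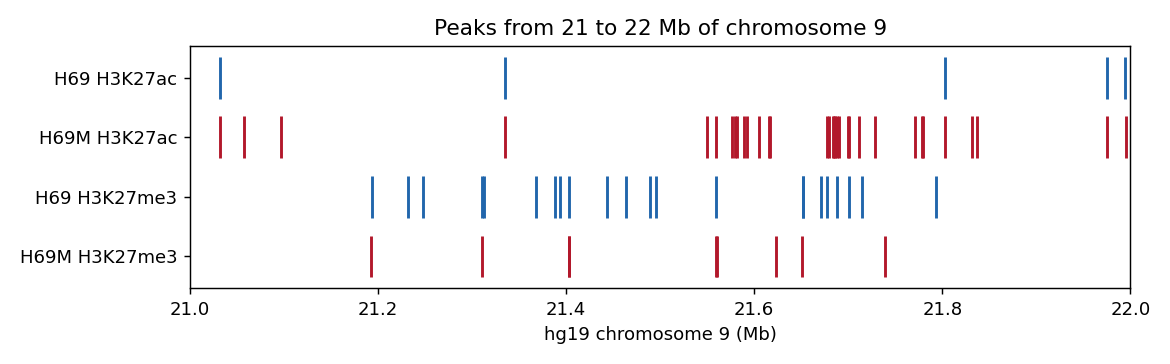
Midpoints of peaks from 21 to 22 Mb of hg19 chromosome 9 (horizontal axis, Mb), with a row for each line and mark and a vertical line for each peak, H69 in blue and H69M in red. H69M has 33 H3K27ac peaks against 5 in H69, with 29 of them beyond 21.5 Mb, and 9 H3K27me3 peaks against 22 in H69.

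Among other windows with immune genes, the H3K27ac ratio was 2.31 in the CXC chemokine window on chromosome 4 (47.7 and 110 kb), 2.20 in the IFIT window on chromosome 10, which holds interferon-induced antiviral genes (8.54 and 18.8 kb), and 1.72 in the GBP window on chromosome 1, which holds interferon-induced GTPases (13.1 and 22.5 kb). The leukocyte receptor window on chromosome 19 had a ratio of 1.40 (86.1 and 120 kb), below that over all peaks. These ratios lay at percentiles 75.5, 61.5, 41.5 and 43.0 of their matched windows, and windows without immune genes had ratios above 1 as well. H3K27me3 was sparse in the chemokine, IFIT and GBP windows, with 7 and 16 peaks in the chemokine window, 0 and 2 in the IFIT window and none in the GBP window in either line. The leukocyte receptor window held 371 and 547 H3K27me3 peaks (81.2 and 96.6 kb, ratio 1.19), and its ratio was 0.819 under equal numbers of peaks.

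The windows around the HOX clusters, homeobox genes that set position along the body axis, held peaks of both marks in both lines. H3K27ac ratios were 1.45 for HOXA (40.7 and 59.2 kb), 1.65 for HOXB (143 and 237 kb) and 1.36 for HOXC (87.9 and 120 kb). H3K27me3 ratios were 0.978 for HOXA (7.43 and 7.27 kb), 1.25 for HOXB (15.95 and 19.9 kb) and 0.879 for HOXC (20.2 and 17.8 kb). The protocadherin clusters on chromosome 5, adhesion genes of neurons, had an H3K27me3 ratio of 0.665 (9.94 and 6.61 kb, percentile 5 of 160) and an H3K27ac ratio of 1.64 (23.1 and 37.9 kb). H3K27me3 was longer in H69M in the zinc finger window 19p12 (4.52 and 16.9 kb, ratio 3.73, or 2.30 without peaks within 2 Mb of the peak-free stretch) and in the type I keratin window on chromosome 17 (5.87 and 15.8 kb, ratio 2.69). It was shorter in the zinc finger window 19q13.4 (24.5 and 20.1 kb, ratio 0.818), in the histone gene window on chromosome 6 (9.18 and 7.80 kb, ratio 0.850) and in the type II keratin window on chromosome 12 (4.76 and 4.11 kb, ratio 0.864). The metallothionein window on chromosome 16, genes that bind metal ions, had an H3K27ac ratio of 2.003 (15.8 and 31.7 kb). Equal numbers of peaks moved H3K27me3 ratios by over 1.5 times in some of these windows, to 0.570 for HOXC, 2.22 for 19p12, 1.007 for CXC chemokines (from 1.88), 0.539 for 19q13.4, 0.501 for the histone window and 0.576 for type II keratins. Of the 17 windows with H3K27ac in H69, 17 had a ratio above 1, and of the 14 with H3K27me3, 6 had a ratio above 1 and 8 below, or 4 and 10 under equal numbers of peaks. A further 3 windows had H3K27me3 peaks in H69M and none in H69.

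**Figure D4:**
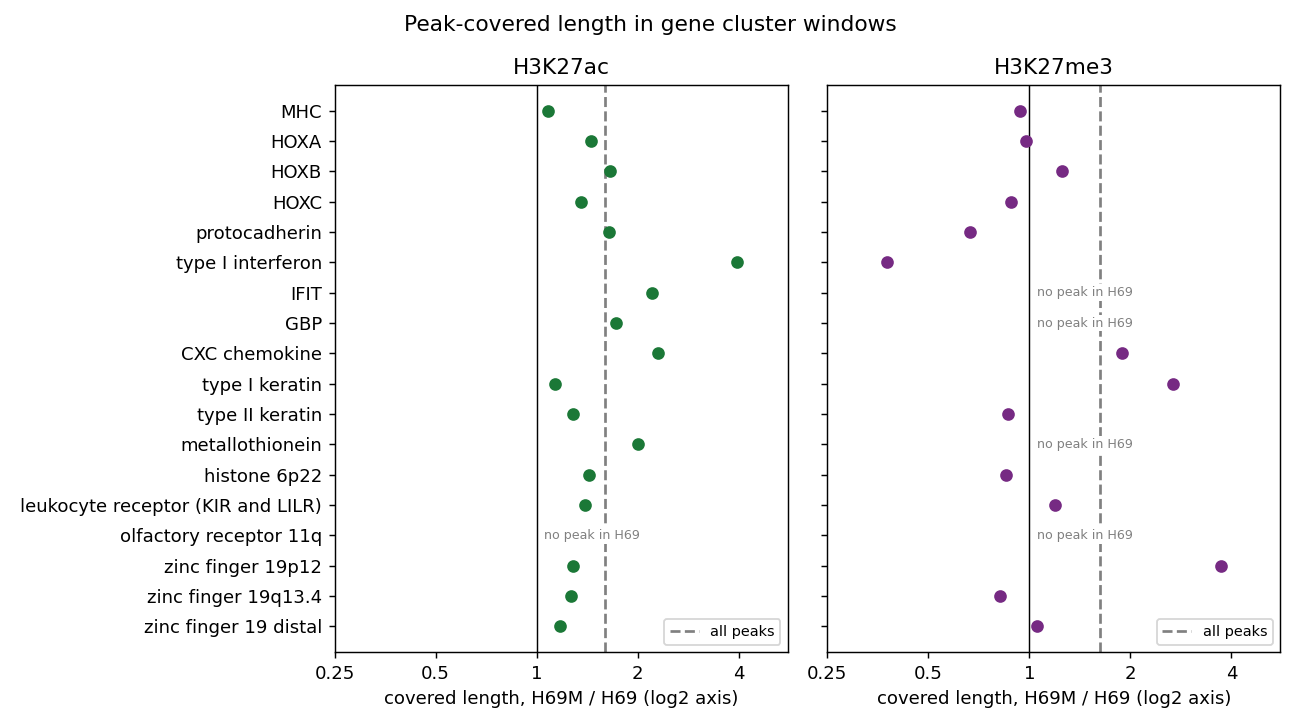
Ratio of the length covered by peaks, H69M over H69 (horizontal log2 axis, no unit), in 18 gene cluster windows (rows), with H3K27ac on the left and H3K27me3 on the right, the black line at a ratio of 1 and the dashed line at the ratio over all peaks, 1.59 and 1.62. The type I interferon window stands farthest to the right for H3K27ac at 3.94 and farthest to the left for H3K27me3 at 0.377.

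Within each line the marks were rarely on the same ground. In H69, 308 of the H3K27ac peaks overlapped an H3K27me3 peak (0.805%, 0.718 to 0.900), and in H69M 795 did (1.56%, 1.45 to 1.67). Circular shifts gave a mean of 457 in H69, so the observed number was 0.675 of it, and 917 in H69M, where it was 0.867. The planned one-sided permutation test looked for more overlap than the shifts and gave p = 1 in H69 and p = 0.989 in H69M. In the lower tail p was 0.001 in H69, the smallest possible, and 0.013 in H69M. The H69M deficit depended on the settings, with a lower-tail permutation p of 0.37 under equal numbers of peaks and of 0.001 with shifts of 100 to 500 kb (ratio 0.715).

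The last comparison asked whether regions that lost one mark in H69M carried the other. Of the 14587 H3K27me3 peaks found only in H69, 348 overlapped an H3K27ac peak found only in H69M (2.39%, 2.14 to 2.65). In the opposite direction 405 of the 30681 H3K27me3 peaks found only in H69M overlapped an H3K27ac peak found only in H69 (1.32%, 1.20 to 1.45). The strongest H3K27me3 peaks of these sets lay at chromosome 18 12308296 to 12309337 in H69 (score 349.9), under an H69M H3K27ac peak with a score of 2065, and at chromosome 20 23029071 to 23030571 in H69M (score 969.5), under an H69 H3K27ac peak with a score of 478.5. Both were chosen after their values were seen.

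Circular shifts gave a mean of 162 overlaps for the first direction and 98.5 for the reverse, so the observed numbers were 2.15 and 4.11 times as high, with a one-sided permutation p of 0.001 for each, the smallest possible. Shifts of only 100 to 500 kb gave ratios of 1.62 and 3.001, and peaks above the H69 median score gave 3.21 and 8.05. The same peaks overlapped the H3K27ac peaks found only in their own line at ratios of 0.660 in H69 (34 of 14587) and 1.33 in H69M (433 of 30681). The one-sided permutation p for more overlap was 0.99 in H69 and 0.001 in H69M. With shifts of 100 to 500 kb the H69M ratio was 1.20 (permutation p of 0.005). For H3K27me3 found only in H69M the excess was therefore not confined to H3K27ac of the other line, though its ratio was lower in its own line. H69 H3K27me3 peaks that were shared with H69M overlapped H3K27ac found only in H69M more often (291 of 7051, 4.13%, 3.67 to 4.62) than those found only in H69 did, so this overlap was not specific to lost H3K27me3.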

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

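The tests of repeats in every H69M library, of copy number and of exchange at single peaks were chosen after the results they bear on had been seen. Peaks on unplaced contigs entered no comparison and were in each list above the 3 that a count of 0 allows. There were 26 H3K27ac peaks on such contigs in H69 and 59 in H69M, and 65 H3K27me3 peaks in H69 and 607 in H69M. As a percent of the list the H3K27me3 peaks on contigs were 5.26 times as frequent in H69M (4.06 to 6.90), and the H3K27ac peaks 1.70 times (1.054 to 2.81).

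H3K27me3 peaks of H69M also gathered beside the largest peak-free stretch of each chromosome, with 445 peaks within 2 Mb in H69 (2.06%) and 2950 in H69M (7.79%), a ratio of 3.79 (3.43 to 4.20). Repeat signal present in every H69M library would raise H3K27ac there too, but its ratio beside the stretches was 0.967 (0.873 to 1.07). On the contigs H3K27ac was also higher in H69M, so this argues against it for the stretches only. More weak calls alone would leave peaks of high score alike. Among peaks with a score of 150 or more, 1150 in H69 and 3222 in H69M, the ratio was 4.01 (2.76 to 6.04). A score may not mean the same at different depth, so weak signal raised past 150 in a deeper H69M library is not excluded. Repeat signal in the H69M H3K27me3 library alone and greater depth or enrichment of that library stay open. So do a different use of the input in peak calling and a true H3K27me3 difference between the lines beside these stretches. None of these was tested.

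Of the 6023 H69M H3K27ac peaks at the score ceiling, 90 had no overlapping H69 peak (1.49%, 1.20 to 1.83), against 4 of 3417 in the other direction (0.117%). Complete loss in H69 of segments that span whole 1 Mb bins would place most of them in bins with no H69 peak of either mark, but 1.11% lay in such bins (0.0281 to 6.04). An H69 peak elsewhere in a bin says nothing about loss of a part of that bin. Greater depth or enrichment of the H69M library, loss of shorter segments and a difference in regulatory activity between the lines stay open, and none of these was tested.

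The marks moved weakly in opposite directions over 1 Mb bins. Spearman's rho between their log2 ratios was -0.107 over 1086 bins, with a permutation p of 0.002 from circular shifts. Replacement within bins needs this sign, but the sign only restates the pattern and is no separate evidence for replacement. Copy number changes alone would give a positive rho if peaks were called without the input as control. Whether the input served as control is not given, so the sign of rho does not settle this. Whether copy number changes act in part of the bins was not tested. At single peaks the comparison with shared peaks of the same score class differed by direction. H3K27me3 peaks found only in H69M lay over H69-only H3K27ac more often than shared ones (odds ratio 2.22, 1.71 to 2.88). Without regard to score the percents overlapped (1.32%, 1.20 to 1.45, against 1.19%, 0.948 to 1.46). Shared peaks carry H3K27me3 in H69 too, where the marks overlapped at 0.675 of the shifted number. An odds ratio above 1 can therefore arise without exchange. In the score class from 150 up the median scores also differed, at 189.9 for H69M-only and 264.2 for shared peaks. In the other direction, H69 peaks without a counterpart lay over H69M-only H3K27ac less often than shared ones (0.727, 0.609 to 0.869). The odds ratios treat peaks as independent, and bins are not replicates of the lines.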

How the results depend on the processing

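The planned promoter and gene list alternatives were not run, since those results were not computed, and no replicate could be left out with 1 library per group. Shifts of 100 to 500 kb, the removal of H3K27me3 peaks near peak-free stretches (in windows too) and the comparison with shared peaks were chosen after seeing the data. Depth is unknown, so a peak missing from a list was not detected there rather than absent. Ratios of peak number and covered length between the lines stayed above 1 in all of these alternatives that were run on them, except that equal peak numbers fix the number ratio at 1 and gave none. Equal numbers keep every H69 peak but only the highest scoring H69M peaks, which favours wide H69M peaks if score and width rise together. H69M H3K27ac peaks shared with H69 had a median score of 896 and width of 1673 bp, against 109 and 808 bp for the others. Overlaps of H3K27me3 found only in a line with H3K27ac found only in the other stayed above the shifts in each alternative run on them, with a one-sided permutation p of 0.001, and with ratios of 1.62 to 3.21 for H3K27me3 found only in H69 and 3.001 to 8.05 for the reverse.

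Percents of shared peaks, for H69 and H69M H3K27ac and then H69 and H69M H3K27me3, were 88.3, 59.9, 34.2 and 20.96 above the H69 median score, 71.5, 62.2, 26.8 and 25.8 with equal peak numbers, 76.2, 50.9, 26.4 and 14.5 with an overlap of 50% of the shorter peak, and 79.4, 57.5, 33.3 and 23.6 after merging. The H69M H3K27me3 percent was 19.9 without peaks near peak-free stretches. The ratio of H69M H3K27ac over H69M H3K27me3 to the shifts no longer passed in the lower tail at 0.916 above the median score, 0.972 with equal numbers and 0.908 with the 50% overlap, and the cause was not tested. The percent of bins longer in H69M was 81.9 for H3K27ac and 44.5 for H3K27me3 with equal numbers, the latter reversed by taking away the weakest H69M peaks, and 97.5 and 68.5 with 5 Mb bins. Equal numbers also reversed the H3K27me3 ratio in the leukocyte receptor window (0.819) and the distal chromosome 19 zinc finger window (0.669, from 1.055). Of the other window ratios, 22 stayed within 1.5-fold and 7 moved further without changing direction.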

Other observations

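Wide H3K27ac peaks were more numerous in H69M, with 921 of 5 kb or more against 328 in H69, and 94.2% and 99.1% of them overlapped a peak of the other line. The widest in H69 lay on chromosome 22 at 30096105 to 30118055, and the widest in H69M on chromosome 9 at 136736574 to 136761034. Both were overlapped by peaks of the other line. H69M also had a peak of 23.2 kb at the lower-coordinate end of the HOXB window, at chromosome 17 46062081 to 46085281. The H69 peaks that overlapped it had a total length of 22.9 kb, which may reach beyond it. The widest H3K27me3 peaks of H69M lay on chromosome 8, with 14.5 kb at 86561913 to 86576434 and 10.4 kb at 86782034 to 86792439, and both were overlapped in H69. A peak of 5.62 kb on chromosome 2 at 53315165 to 53320787, with a low score of 75.19, was listed in H69 only.

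Among the 650 bins with at least 8 H69 H3K27me3 peaks, 99 had at most 50% of the H3K27me3 length left in H69M. In 44 of these 99 bins (44.4%, 34.5 to 54.8) the H3K27ac length was at least doubled, against 130 of the 551 other bins (23.6%, 20.1 to 27.4). The intervals treat bins as independent, although neighbouring bins are among the 44. The 551 bins were not matched to the 99 on covered length in H69, and large ratios come more easily from small lengths. The largest H3K27ac ratios among the 44 were on chromosome 6 from 45 to 46 Mb (1.43 kb in H69 and 26.6 kb in H69M) and from 11 to 12 Mb (4.46 and 61.4 kb), and on chromosome 12 from 116 to 117 Mb (2.49 and 30.7 kb). In the olfactory receptor window on chromosome 11, with no H3K27ac peak in either line, H3K27me3 was listed with 0 peaks in H69 and 26 in H69M over 4.83 kb, and all 26 lay within 2 Mb of the peak-free stretch of that chromosome. These bins and the wide peaks were chosen after their values were seen.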
